A study of Mus musculus with 6 samples.

How the data were processed

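RNA from primary stromal cells of 8 to 12 week old C57BL/6 mouse prostates was measured in 3 libraries of cells with a lentiviral vector and 3 libraries of cells with the vector carrying S37A β-catenin. Per the labels' protocols, dissociated prostate cells were grown on collagen with 1e-10 M dihydrotestosterone, and after a short replating step the cells that had not attached were discarded. Per the same protocols, complementary DNA was made with a SMART-Seq v4 kit from random and oligo(dT) primers and sequenced on an Illumina HiSeq. That kit does not mark the strand, so reads from a gene and from an overlapping antisense gene cannot be told apart. Groups and replicate numbers were taken from the sample titles.

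Per the submitters' processing notes, bcl2fastq 1.8.3, TopHat and Cufflinks were used with the mm10 build, without versions for TopHat and Cufflinks. Each deposited file holds, per the file headers, the FPKM of each transcript model with the lower and upper bound of its confidence interval, a coverage value, a length and a status. The coverage, a signal over the model in the authors' deposited files, was a constant multiple of the FPKM within a library and was used only to compare the depth of the libraries. Read counts are not in these files. Fragment numbers inferred from interval widths came out whole, within 0.02, for 86.5% to 87.6% of models with up to 10 fragments but only 9.00% to 9.75% of models above 30 fragments, so whole reads could not be recovered and the count models planned for that case were not run. The depth given for each library is likewise inferred from the interval widths and covers counting error only.

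FPKM values of models with the same symbol were summed, and 5 genes whose status was other than OK in a library (Dag1, Eftud2, Fhl1, Nrp2 and Trim32) were left out. The 12022 genes with a mean of at least 0.5 FPKM over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 (R 4.3.3), with an intensity trend, no block, and Benjamini-Hochberg adjustment at 0.05. Differences are S37A minus vector on that log2 scale, which understates changes of genes with low FPKM. Ratios of mean FPKM of single genes are given without a pseudocount, and 2-fold means at least 1 on the log2 scale. Median log2 ratios of the lists of other myeloid and other blood genes have 0.05 FPKM added to both means. Gene positions are from GENCODE M21 on mm10, in 1-based coordinates: 23105 of 23268 uniquely named symbols lay at an overlapping position in the files.

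Before the data were examined, the groups, the tests, the alternatives and 33 gene lists were fixed, the lists from general knowledge. They cover Wnt feedback genes, other Wnt targets, Wnt ligands, Wnt receptors and antagonists, TGF-β family ligands, TGF-β and BMP responses, stromal growth factors, smooth muscle, fibroblast matrix, proteases, cell cycle, p53, inflammatory, interferon, androgen, adipogenic, osteochondrogenic, Hedgehog, Notch, hypoxia, cholesterol, stress and immediate-early genes, and markers of other cell types and of RNA quality. The list of genes encoded by mitochondrial DNA had 0 of its 15 members in the files, so 32 lists were tested. Camera with a preset inter-gene correlation of 0.01 was the main list test, adjusted over the lists, and camera with an estimated correlation and fry were alternatives. Of the 32 lists, 23 were called with the preset correlation, 21 up and 2 down. Camera with the estimated correlation called 0, with 12 at an unadjusted p under 0.05, and fry called 15. The median log2 difference of all tested genes was -0.07, so camera can call a list up whose own median is near 0. The p53, adipogenic, Hedgehog, stress and endothelial lists had negative medians with an upward camera direction, none of them called; camera placed the stress list down under quantile normalization. Median-ratio scaling made each of these 5 medians positive, quantile normalization all but that of the stress list, and removal of the 100 most abundant genes those of p53, Hedgehog and endothelium. The glial list had a positive median and a negative mean.

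Genes named are Ctnnb1, Axin2, Lef1, Nkd1, Tgfb1, Tgfb2 and Tgfb3; the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 2 FPKM in the higher group and no overlap of the groups; and members of each list among the 4 with the smallest p. In the ranking 2 genes, Snora28 and 2700081O15Rik, were passed over as a small RNA and a predicted gene. Csf1r, Cd14 and Cdc20 were named after their values were seen. Some genes that meet these criteria are not reported here.

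The script was tested on simulated data with the real means and spreads of the 12022 genes. With 200 genes changed by 0.25, 0.5 and 1 on the log2 scale, the S37A against vector comparison recovered 0%, 84.5% and 98% of them, with 0, 11 and 8 false calls, and with no change it made 0 calls. In the real data 3122 genes were called, which makes the adjusted threshold less strict than with 200 changed genes. The recovered shares therefore do not give the power of the real comparison. Of the 32 lists without a change camera called 0, and it called a list whose members were shifted by 0.2. The simulated genes varied independently of each other, so the list test was not checked on correlated genes, and its p-values in the real data may be too small. Pairs of libraries within a group differed 1.67 to 4.72 times as much as counting alone gives, and pairs between groups 6.70 to 12.7 times. A spread above counting error can also come from library preparation, so it does not show whether the libraries are separate cultures; they were treated as separate samples because the titles number them as replicates. Paralogs and overlapping genes are uncertain, since the deposited values do not show how shared reads were assigned.

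Alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no expression filter, a filter of 5 FPKM, median-ratio scaling, quantile normalization, removal of the 100 most abundant genes, limma without the trend, sample weights, a replicate block, each library left out, and transcript models kept apart. Added after seeing the data were genes with 1 transcript model only, removal of trends on GC content and length, and comparison of list medians with 10000 random lists matched on mean FPKM.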

Results

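RNA was sequenced from primary stromal cells grown out of C57BL/6 mouse prostate that carried either a lentiviral vector or the same vector with the S37A form of β-catenin. β-catenin, the product of Ctnnb1, carries the canonical Wnt signal into the nucleus, and its S37A form lacks a serine whose phosphorylation marks the protein for breakdown. There were 3 vector libraries and 3 S37A libraries, and the question was which transcripts differ in level between the 2 groups. Expression was given as FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of a library) for 34535 transcript models, summed to 24346 gene symbols. The width of the confidence intervals beside the FPKM values corresponded to 48.6, 51.0 and 46.2 M fragments in the vector libraries and 46.9, 40.7 and 43.9 M in the S37A libraries. Between 10959 and 11093 genes reached 1 FPKM in each library. Group values below are mean FPKM ± SD over n = 3 libraries, and adjusted p-values of genes are from limma with Benjamini-Hochberg adjustment. The labels do not say whether the libraries of a group came from separate cultures or animals, so the p-values measure the spread between these samples, which may be technical.

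Ctnnb1 itself, on chromosome 9 from 120929216 to 120960507 (mm10, plus strand, protein-coding), was higher in S37A. Its level was 116, 99.1 and 116 FPKM in the vector libraries and 132, 144 and 146 FPKM in the S37A libraries, so that the groups did not overlap. The log2 difference was 0.35 (SE 0.07, limma adjusted p = 0.0158). An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 libraries against 3 allow. Ctnnb1 was no longer called by limma without S37A replicate 2 (adjusted p = 0.0534) or without S37A replicate 3 (adjusted p = 0.0585), and its adjusted p over all alternatives ran from 0.00321 to 0.0585. Reads from the introduced coding sequence and from the cells' own gene are not separated in the deposited values.

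Several negative-feedback targets of the Wnt pathway rose in S37A. Axin2, which encodes a scaffold of the β-catenin destruction complex and is transcribed in response to Wnt signals, lies on chromosome 11 from 108920349 to 108950783. It went from 0.131 ± 0.0385 to 2.95 ± 0.296 FPKM, a 22.5-fold ratio of means (adjusted p = 3.85e-05). Nkd1, an inhibitor of Dishevelled on chromosome 8 from 88521354 to 88594884, rose from 0.946 ± 0.0443 to 2.27 ± 0.309 FPKM (adjusted p = 0.00291). Tcf7, a DNA-binding partner of β-catenin, rose from 0.728 ± 0.129 to 2.01 ± 0.278 FPKM, and the secreted modulator Dkk2 from 5.89 ± 0.829 to 10.5 ± 1.27 FPKM (adjusted p = 0.00353 and 0.00744). Lef1, another factor of that family, stood at 3.17 ± 0.324 and 3.41 ± 0.102 FPKM in vector and S37A and did not pass the test (adjusted p = 0.338). Of the 10 feedback genes above the expression filter, 5 rose, 0 fell and 5 did not pass, and 5 rose when adjusted over the list alone. Camera, which compares a list with all other genes, called the list up (adjusted p = 1.93e-07; 0.0950 with the inter-gene correlation estimated from the data; 2.34e-08 to 0.0950 over alternatives). None of the lists below was called with the estimated correlation. As the median log2 difference of all genes was -0.07, camera can call a list up whose own median is near 0. With the preset correlation, other splits of the 6 libraries into 3 and 3 also gave 4 to 23 called lists, with at most 2 genes called in a direction. A range given as over alternatives is that of the adjusted p of the same result in all other settings tried, and no called list changed direction under another scaling. Where numbers of genes are given for the 3 other scalings, the order is median-ratio scaling, quantile normalization and removal of the 100 most abundant genes. The last of these also takes some list members out of the test, so its counts mix scaling with removal.

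**Figure D1:**
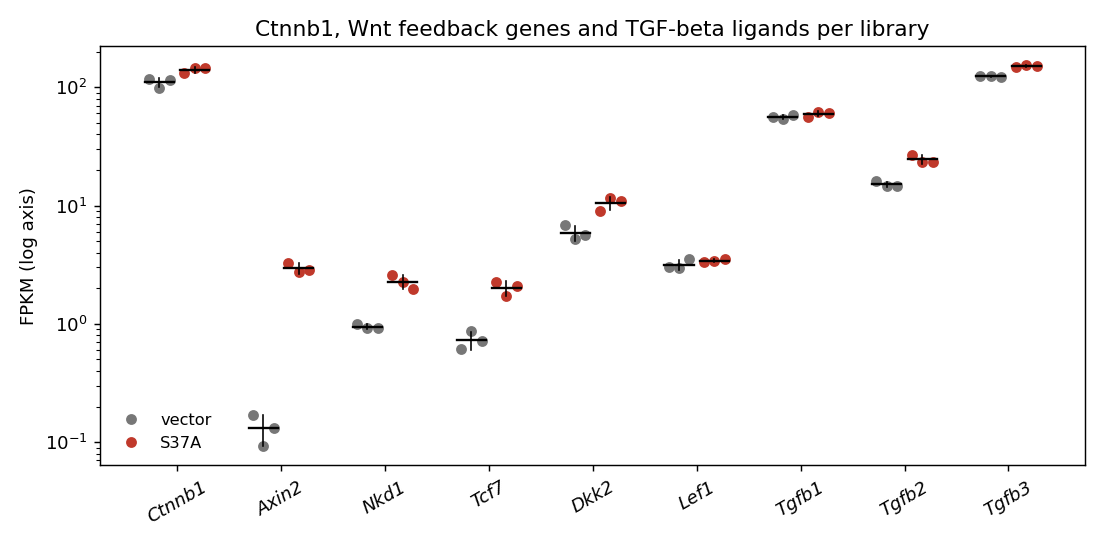
FPKM of Ctnnb1, 5 Wnt feedback genes and 3 TGF-β ligands in the 3 vector (grey) and 3 S37A (red) libraries on a log axis; points are libraries, horizontal lines group means and vertical lines 1 SD. Every S37A library lies above every vector library for Axin2, Nkd1, Tcf7, Dkk2, Tgfb2, Tgfb3 and Ctnnb1, and the groups overlap for Lef1 and Tgfb1.

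Across the 12022 genes tested, 729 were higher and 2393 lower in S37A, with most differences small: the median size among called genes was 0.24 on the log2 scale. Numbers of list members that fell are to be read against this share of lower genes. It was not exceeded by p53 genes (4 of 21 lower), proteases (4 of 21), ribosomal protein genes (3 of 24) or Hedgehog genes (1 of 8). At a difference of at least 2-fold, 16 genes were higher and 10 lower. Among those lower are Clk2-scamp3, Ppip5k1 and 2700081O15Rik, listed at 0 in every S37A library. Such a 0 may come from reads moving among overlapping transcript models. The groups did not overlap for 5751 genes, or 47.8%, where chance gives 10% for a single gene in 3 libraries against 3. All genes share the same libraries, whose median-ratio scaling factors also lay apart, at 1.017 to 1.036 in vector and 0.963 to 0.982 in S37A. A difference in scale can therefore add to this share. The split between higher and lower depended on the scaling of the libraries. With median-ratio scaling 1243 genes were higher and 978 lower, with quantile normalization 1094 and 957, and without the 100 most abundant genes 912 and 1522. Leaving out 1 library lowered the counts in 5 of 6 cases: 467 higher and 1202 lower without vector replicate 2, 475 and 1255 without vector replicate 3, 600 and 1373 without S37A replicate 1, 358 and 867 without S37A replicate 2, and 298 and 606 without S37A replicate 3.

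Bex1 had the largest fitted rise among genes that met the criteria for naming. This gene (chromosome X, 136213972 to 136215513, minus strand) encodes a small adaptor protein, and it went from 0.984 ± 0.193 to 17.4 ± 3.37 FPKM, a 17.7-fold ratio (adjusted p = 5.04e-05). Calca and Calcb, which encode calcitonin gene-related peptides, rose from 0.420 ± 0.221 to 4.51 ± 0.0720 FPKM and from 4.58 ± 2.05 to 21.9 ± 2.84 FPKM (adjusted p = 0.000168 and 0.00498). They are paralogs on chromosome 7, at 114631478 to 114636357 and 114718643 to 114723365, so the share of reads given to each is uncertain. Stra6, the cell-surface receptor for retinol-binding protein, on chromosome 9 from 58063788 to 58153996, rose from 1.17 ± 0.135 to 6.31 ± 0.819 FPKM (adjusted p = 0.000149). The other rises in the first 10 were Axin2 and 5 genes typical of macrophages, namely Tyrobp, C1qa, Lyz2, Ctss and C1qc.

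Among the falls, Ccl2 and Ccl7, which encode chemokines that attract monocytes, lie on chromosome 11 at 82035571 to 82037453 and 82045712 to 82047525. Ccl2 fell from 114 ± 16.7 to 43.0 ± 2.42 FPKM and Ccl7 from 80.5 ± 15.6 to 37.8 ± 3.49 FPKM (adjusted p = 0.00113 and 0.00558). Nfkbiz, a regulator of NF-κB target genes on chromosome 16 from 55811375 to 55838899, fell from 22.1 ± 0.988 to 9.06 ± 0.548 FPKM (adjusted p = 7.58e-05), and the chemokine gene Ccl20 from 3.99 ± 1.12 to 1.28 ± 0.362 FPKM (adjusted p = 0.00982). Spata4, Gp5, Cep85l and Tlcd2 fell to between 0.358 and 0.523 of their vector level. Ppip5k1, which encodes an inositol phosphate kinase on chromosome 2 from 121310561 to 121355396, was listed at 2.48, 2.49 and 2.28 FPKM in the vector libraries and at 0 in every S37A library. The read-through annotation Clk2-scamp3 was listed at 8.57, 8.81 and 8.86 FPKM in the vector libraries and at 0 in every S37A library; it overlaps Clk2, which was listed at 0 in all 6 libraries, and Scamp3. No fold is given for these genes, because a listed 0 can come from how reads were assigned among overlapping models, even with a status of OK.

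Secreted ligands of the TGF-β family rose more often than they fell. Tgfb2 (chromosome 1, 186622792 to 186705989, minus strand) went from 15.1 ± 0.812 to 24.5 ± 2.05 FPKM, and Tgfb3 (chromosome 12, 86056745 to 86079041, minus strand) from 124 ± 1.37 to 150.4 ± 2.71 FPKM (adjusted p = 0.00271 and 0.00353). Tgfb1 stood at 56.2 ± 2.26 and 59.6 ± 2.97 FPKM and did not pass (adjusted p = 0.220). Inhbb, an activin subunit, rose from 8.11 ± 0.522 to 13.9 ± 1.77 FPKM, while the stress-induced ligand Gdf15 fell from 10.6 ± 0.534 to 6.96 ± 0.314 FPKM (adjusted p = 0.00456 and 0.00231). Of 17 ligand and latency genes tested, 5 rose and 1 fell, or 6 and 2 adjusted over the list alone. Camera called the list up (adjusted p = 0.00149; 0.116 with an estimated correlation; 8.90e-05 to 0.116 over alternatives). Without vector replicate 2, 2 members fell.

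Among Wnt ligands and R-spondins, Wnt2 rose from 2.60 ± 0.396 to 4.87 ± 0.451 FPKM and Wnt11 from 1.14 ± 0.112 to 2.28 ± 0.218 FPKM (adjusted p = 0.00567 and 0.00369). Rspo3, a secreted enhancer of Wnt signalling, fell from 18.8 ± 3.37 to 14.3 ± 0.501 FPKM (adjusted p = 0.0453), a call lost under each other scaling, without a filter, without the trend, with the replicate block, and with any 1 library but vector replicate 1 left out. Of 6 genes tested, 2 rose and 1 fell, or 3 and 1 adjusted over the list alone. This list was called up (adjusted p = 0.00581; 0.213 with an estimated correlation; 0.00225 to 0.299 over alternatives). The call was lost among genes with a mean FPKM of at least 5 (adjusted p = 0.299) or with 1 transcript model (adjusted p = 0.09998).

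Paracrine growth factors and IGF-binding proteins moved in both directions. Igf1 rose from 14.0 ± 0.753 to 19.7 ± 1.24 FPKM and Igfbp2 from 125 ± 13.3 to 187 ± 3.01 FPKM (adjusted p = 0.00494 and 0.00456). The lymphatic growth factor Vegfc fell from 28.7 ± 0.127 to 19.1 ± 0.271 FPKM, and Kitl, the ligand of the receptor Kit, from 12.5 ± 0.514 to 9.48 ± 0.403 FPKM (adjusted p = 0.000229 and 0.00567). Of 29 genes tested, 7 rose and 4 fell, or 7 and 4 adjusted over the list alone. Their median log2 difference was only 0.02, against -0.07 for all genes. Camera called them up as a list (adjusted p = 0.00492; 0.111 with an estimated correlation; 0.00141 to 0.702 over alternatives), but not under quantile normalization (adjusted p = 0.0547), and fry, which asks whether members move one way on balance, did not (adjusted p = 0.702).

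Of 17 receptors and secreted antagonists of Wnt, 3 rose and 0 fell, with the same counts adjusted over the list alone. Fzd1, a Frizzled receptor, rose from 8.76 ± 0.757 to 16.8 ± 0.970 FPKM and the co-receptor Ror1 from 1.38 ± 0.237 to 2.14 ± 0.152 FPKM (adjusted p = 0.00125 and 0.0160; Ror1 0.0588 without S37A replicate 3 and 0.00331 to 0.0588 over alternatives). The 3 other scalings gave 5, 4 and 5 rising. Camera called the receptors up (adjusted p = 0.000991; 0.116 with an estimated correlation; 0.000429 to 0.116 over alternatives). Genes reported as Wnt targets in some cell types were mixed: of 25 tested, 6 rose, among them Twist1 (from 9.09 ± 0.322 to 11.5 ± 0.185 FPKM), and 2 fell, among them Myc (from 51.1 ± 3.37 to 41.1 ± 0.358 FPKM), with the same counts adjusted over the list alone. Camera called these targets up (adjusted p = 0.00297; 0.111 with an estimated correlation; 0.00165 to 0.111 over alternatives). Without vector replicate 3 and S37A replicates 1, 2 and 3, 2, 3, 2 and 1 of them rose. Without vector replicate 2, vector replicate 3, S37A replicate 1 or S37A replicate 3, 1 fell, as under quantile normalization and, among 17 genes, with 1 transcript model per gene. With the replicate block 3 rose. With sample weights 9 rose and 5 fell.

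Genes induced by TGF-β in fibroblasts rose in 6 of 21 cases and fell in 1, or 8 and 1 adjusted over the list alone. Bhlhe40, a transcriptional repressor, rose from 53.8 ± 6.85 to 80.3 ± 7.92 FPKM, while the ubiquitin ligase Smurf1 fell from 34.4 ± 3.10 to 26.7 ± 0.507 FPKM (adjusted p = 0.0121 and 0.0113). As a list they were called up (adjusted p = 3.17e-06; 0.111 with an estimated correlation; 8.21e-07 to 0.111 over alternatives), with 2 rising members without S37A replicate 2. It had 4 without a filter, with the replicate block, without S37A replicate 3 or with GC and length trends removed. BMP-induced genes and BMP antagonists rose in 6 of 14 cases and fell in 0, or 6 and 1 adjusted over the list alone. Id1 rose from 81.8 ± 1.43 to 105 ± 4.72 FPKM and Fst, the antagonist of activins, from 39.0 ± 2.71 to 55.7 ± 6.90 FPKM (adjusted p = 0.00411 and 0.0115), and the list was called up (adjusted p = 8.08e-06; 0.0950 with an estimated correlation; 1.28e-06 to 0.0950 over alternatives).

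Most smooth muscle contractile genes tested rose, by small amounts. Actg2, the enteric smooth muscle actin, rose from 912 ± 15.1 to 1182 ± 9.67 FPKM and Cnn1 from 341 ± 4.21 to 455 ± 14.1 FPKM (adjusted p = 0.00161 and 0.00155). Of 17 genes tested, 13 rose and 0 fell, with 15 rising when adjusted over the list alone, and the list was called up (adjusted p = 3.86e-13; 0.0950 with an estimated correlation; 4.71e-15 to 0.0950 over alternatives). Without vector replicate 3 and S37A replicates 1, 2 and 3, the number that rose was 7, 7, 5 and 6. With the replicate block it was 8, without a filter 5, and with the 3 other scalings it was 14, 10 and 5, the last among 10 genes still tested. Pericyte markers rose in 3 of 6 cases by both counts (adjusted over all genes and adjusted over the list alone), with Mcam at 46.4 ± 1.49 and 60.7 ± 2.80 FPKM (list adjusted p = 0.00338; 0.111 with an estimated correlation; 0.000187 to 0.111 over alternatives). Skeletal muscle markers rose in 2 of 4 cases by both counts, namely Des (from 79.8 ± 4.39 to 99.2 ± 0.233 FPKM), which is also in the smooth muscle list, and Acta1 (from 86.0 ± 11.8 to 133 ± 5.49 FPKM). That list was called up (adjusted p = 0.0206; 0.190 with an estimated correlation; 0.00180 to 0.190 over alternatives). Muscle markers were not called under median-ratio scaling (adjusted p = 0.0971), quantile normalization (adjusted p = 0.123) without S37A replicate 3 (adjusted p = 0.0611), without a filter (adjusted p = 0.0789) or by fry (adjusted p = 0.0539).

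Fibroblast matrix genes rose in 6 of 27 cases and fell in 2, with the same counts adjusted over the list alone. Tnc, the glycoprotein tenascin C, rose from 669 ± 23.4 to 849 ± 14.9 FPKM, while Pdgfra, a receptor marking fibroblasts, fell from 18.8 ± 0.861 to 15.8 ± 0.408 FPKM (adjusted p = 0.00355 and 0.0132), a fall not called under median-ratio scaling (adjusted p = 0.0506) or without S37A replicate 3 (adjusted p = 0.0555; 0.00450 to 0.0555 over alternatives). Camera called matrix genes up (adjusted p = 9.19e-08; 0.116 with an estimated correlation; 4.73e-09 to 0.116 over alternatives). Matrix genes under the 3 other scalings numbered 11, 7 and 5 rising and 0, 1 and 2 falling, the last among 19 genes still tested. Without vector replicate 1, 12 rose; 1 fell without vector replicate 2, vector replicate 3, S37A replicate 1 or S37A replicate 2, without a filter, with a mean of at least 5 FPKM, with the replicate block or with 1 transcript model per gene, and 0 without S37A replicate 3. With sample weights 12 rose. Of 21 proteases and inhibitors, 3 rose and 4 fell, or 6 and 4 adjusted over the list alone. This balance turned with scaling: the 3 others gave 6, 4 and 4 rising and 3, 3 and 3 falling, the last among 20 genes. One of the rises is Ctss, which is also a macrophage marker. Timp3, a metalloproteinase inhibitor on chromosome 10 from 86300372 to 86349506, rose from 163 ± 3.27 to 325 ± 17.5 FPKM, and the proteases Mmp9 and Mmp13 fell from 11.3 ± 1.10 to 5.88 ± 0.483 FPKM and from 16.9 ± 2.80 to 8.70 ± 1.03 FPKM (adjusted p = 7.58e-05, 0.00231 and 0.00626). Camera called that list up (adjusted p = 0.00916; 0.342 with an estimated correlation; 0.00173 to 0.342 over alternatives). Proteases were not called under median-ratio scaling (adjusted p = 0.0708), quantile normalization (adjusted p = 0.128), with a mean of at least 5 FPKM (adjusted p = 0.152), with 1 transcript model per gene (adjusted p = 0.0614) or by fry (adjusted p = 0.231).

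**Figure D2:**
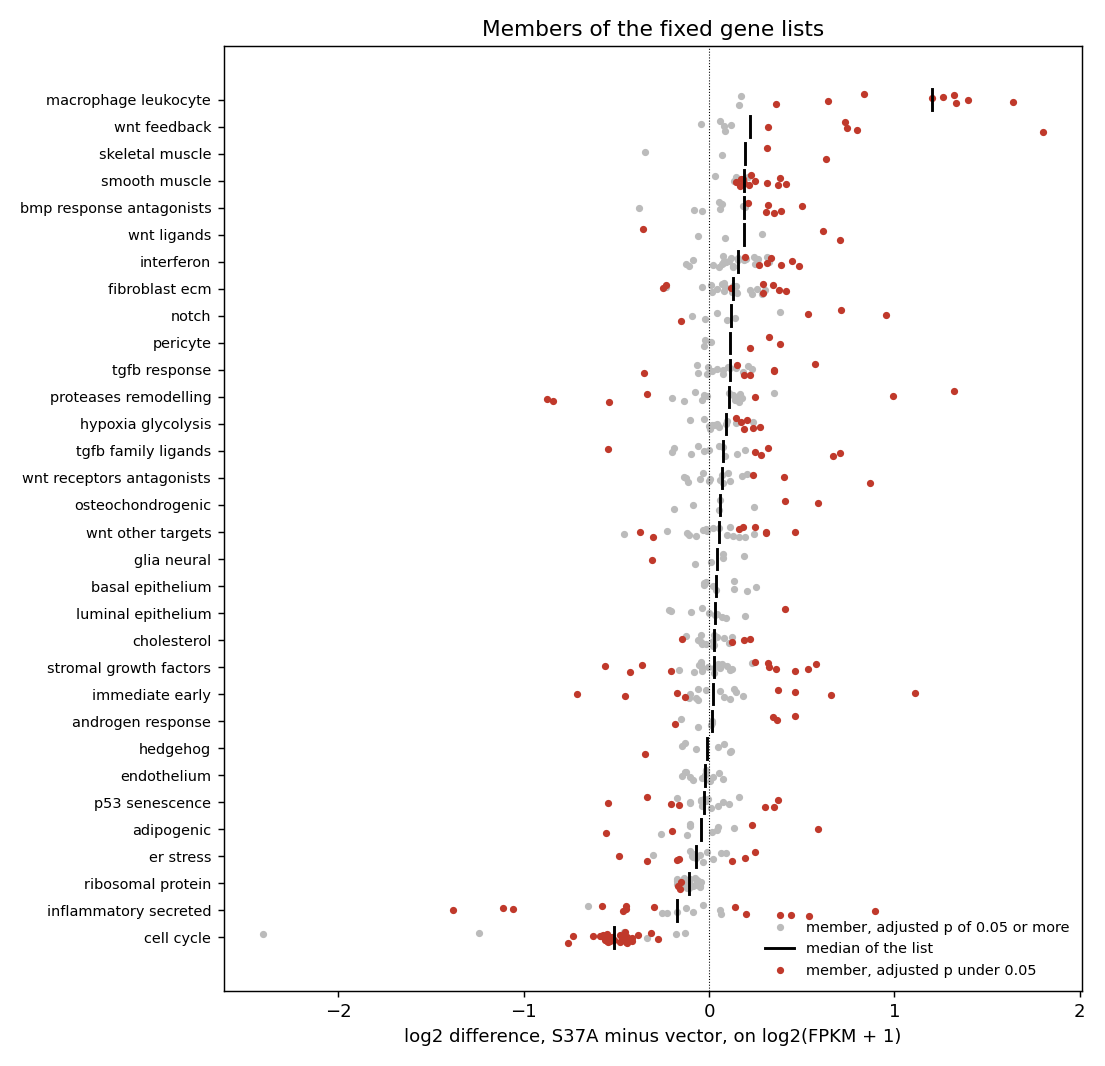
Log2 differences (S37A minus vector, on log2(FPKM + 1)) of the tested members of each fixed gene list; points are genes, red where the adjusted p was under 0.05, and black bars are list medians. Cell cycle genes have a median of -0.51 and macrophage markers a median of 1.20.

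Most proliferation genes tested fell. Of 35 S, G2 and M phase genes tested, 29 fell and 0 rose, with 33 falling when adjusted over the list alone. Top2a, a topoisomerase needed for chromosome separation, fell from 8.39 ± 1.77 to 4.48 ± 0.329 FPKM, Mcm2, part of the replicative helicase, from 11.3 ± 1.81 to 6.91 ± 0.238 FPKM, and the mitotic kinase Cdk1 from 9.06 ± 1.28 to 5.91 ± 0.229 FPKM (adjusted p = 0.0102, 0.00919 and 0.0101). The list median was -0.51 on the log2 scale and camera called it down (adjusted p = 2.80e-08; 0.389 with an estimated correlation; 3.68e-13 to 0.389 over alternatives). It fell under each scaling tried, with 24, 19 and 28 genes called under median-ratio scaling, quantile normalization and without the 100 most abundant genes. Without vector replicate 3, S37A replicate 2 and S37A replicate 3 the number was 17, 11 and 13, and 15 of 18 tested with a mean of at least 5 FPKM. Cdc20 was listed at 8.13, 12.2 and 12.2 FPKM in vector and 0, 0 and 9.67 FPKM in S37A, and did not pass (adjusted p = 0.0721).

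Among 21 p53 targets and cell cycle inhibitors, 3 rose and 4 fell, or 5 and 5 adjusted over the list alone. Trp53 fell from 59.9 ± 3.04 to 47.2 ± 1.53 FPKM and the inhibitor gene Cdkn2b rose from 103 ± 10.3 to 132 ± 3.26 FPKM (adjusted p = 0.00630 and 0.0151; Cdkn2b 0.0503 without S37A replicate 2 and 0.00275 to 0.0503 over alternatives). Camera did not call this list (adjusted p = 0.363), and its median, -0.03, was positive under each of the 3 other scalings, which gave 5, 4 and 5 rising and 2, 2 and 2 falling. Without S37A replicates 2 and 3, 0 and 1 of its members rose, and 2 fell without vector replicate 1, vector replicate 2, S37A replicate 2 or S37A replicate 3, as without a filter. Of these genes 1 fell among the 12 with 1 transcript model.

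Cytokines, chemokines and NF-κB targets moved both ways. Besides Ccl2, Ccl7 and Ccl20, the adhesion molecule Vcam1 fell from 15.9 ± 0.683 to 11.3 ± 0.427 FPKM and Cxcl16 from 4.97 ± 0.215 to 3.32 ± 0.0673 FPKM, while Cxcl14 rose from 4.66 ± 0.589 to 9.50 ± 0.294 FPKM (adjusted p = 0.00301, 0.00271 and 0.00154). Of 23 genes tested, 6 rose and 8 fell, or 6 and 9 adjusted over the list alone; camera did not call the list (adjusted p = 0.947) and fry called it down (adjusted p = 0.0289; 0.0289 to 0.993 over alternatives). This balance turned with scaling: the 3 others gave 7, 7 and 6 rising and 6, 6 and 7 falling, the last among 22 genes. The number that rose was 3 without vector replicate 2, vector replicate 3 or S37A replicate 1, and 2 with the replicate block, with 1 transcript model per gene (17 tested) or without S37A replicate 2 or 3. Interferon-stimulated genes rose in 7 of 31 cases and fell in 0 by both counts, with Ifi27l2a at 133 ± 6.24 and 168 ± 2.54 FPKM (adjusted p = 0.00484), and were called up as a list (adjusted p = 1.38e-08; 0.342 with an estimated correlation; 1.07e-12 to 0.342 over alternatives; 0.305 by fry). Only 2, 1, 2 and 1 of them rose without vector replicates 2 and 3 and S37A replicates 2 and 3, and 1 fell without vector replicate 3. With sample weights 18 rose, and without a filter 3. Macrophage markers rose in the same libraries, in 9 of 11 cases.

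Immediate-early genes, which also respond to handling, rose in 4 and fell in 4 of 20 cases, or 5 and 4 adjusted over the list alone. Nr4a1, an orphan nuclear receptor, rose from 38.2 ± 4.23 to 83.4 ± 4.40 FPKM, while Ier2 fell from 62.0 ± 4.21 to 37.5 ± 2.37 FPKM and Egr1 from 104 ± 6.89 to 75.8 ± 5.46 FPKM (adjusted p = 0.000916, 0.00178 and 0.00770). Camera called the list up (adjusted p = 0.0261; 0.508 with an estimated correlation; 0.0102 to 0.538 over alternatives). Its median log2 difference was only 0.02, against -0.07 for all genes. Immediate-early genes were not called under median-ratio scaling (adjusted p = 0.0577), quantile normalization (adjusted p = 0.175), without vector replicate 2 (adjusted p = 0.128), with a mean of at least 5 FPKM (adjusted p = 0.0997), sample weights (adjusted p = 0.0871), 1 transcript model per gene (adjusted p = 0.130) or by fry (adjusted p = 0.538). With the 3 other scalings there were 6, 6 and 6 rising and 2, 2 and 2 falling. The number that fell was 2 without a filter, with the replicate block and without vector replicate 2, vector replicate 3, S37A replicate 2 or S37A replicate 3, and 6 with sample weights.

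Most macrophage and other myeloid markers tested were higher in S37A. Lyz2, the lysozyme of myeloid cells on chromosome 10 from 117277331 to 117282321, rose from 14.1 ± 1.91 to 36.7 ± 2.63 FPKM and the cathepsin gene Ctss from 1.45, 1.71 and 1.35 FPKM to 6.42, 4.93 and 4.53 FPKM in the 3 libraries of each group (adjusted p = 0.000847 and 0.00161). The signalling adaptor Tyrobp rose from 0.780 ± 0.435 to 4.45 ± 0.424 FPKM, and the complement genes C1qa and C1qc from 0.493 ± 0.287 to 2.91 ± 0.482 FPKM and from 0.478 ± 0.165 to 2.54 ± 0.317 FPKM (adjusted p = 0.00260, 0.00353 and 0.00145). Of 11 genes tested, 9 rose and 0 fell, with 10 rising when adjusted over the list alone. The exceptions over all genes were Csf1r, at 0.497 ± 0.0741 and 0.675 ± 0.0631 FPKM, and Cd14, at 2.92 ± 0.460 and 3.40 ± 0.0977 FPKM (adjusted p = 0.0883 and 0.153). Camera called the markers up (adjusted p = 1.04e-13; 0.0981 with an estimated correlation; 3.19e-16 to 0.0981 over alternatives), with a median log2 difference of 1.20.

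**Figure D3:**
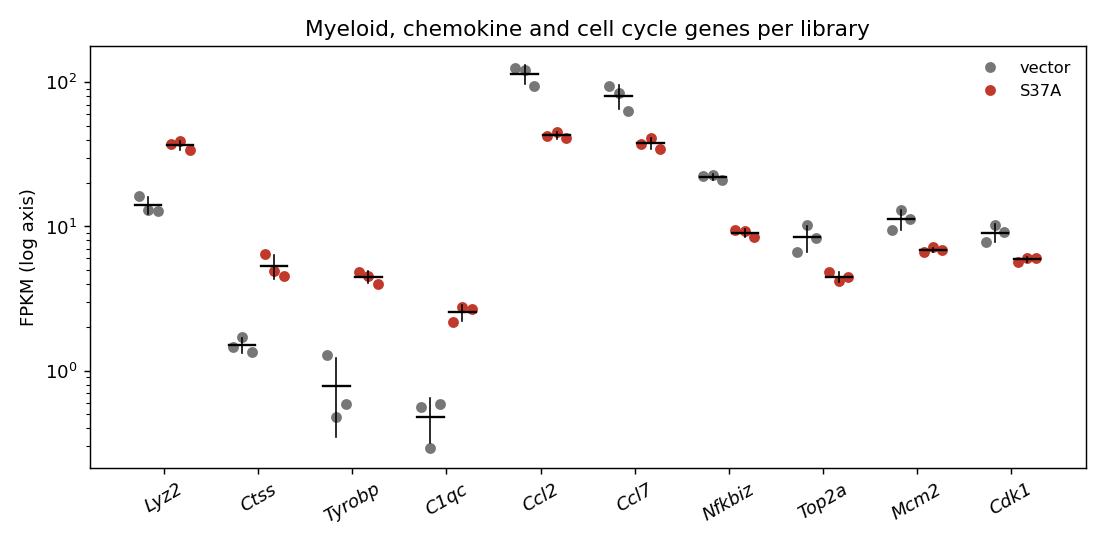
FPKM of 4 myeloid genes, 2 chemokine genes, Nfkbiz and 3 cell cycle genes in the 3 vector (grey) and 3 S37A (red) libraries on a log axis; points are libraries, horizontal lines group means and vertical lines 1 SD. Lyz2, Ctss, Tyrobp and C1qc are higher and the other genes lower in each S37A library than in each vector library.

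Markers of epithelium, endothelium, glia and neurons were called by limma in few cases, unlike the pericyte and skeletal muscle markers given above. Basal epithelial markers changed in 0 of 9 cases by either count, with Krt5 at 0.527 ± 0.154 and 0.790 ± 0.406 FPKM, called only without S37A replicate 1 (list adjusted p = 0.0605; 0.00236 to 0.702 over alternatives). Luminal and general epithelial markers rose in 1 of 11 cases by either count, Cd24a, from 30.5 ± 4.56 to 40.7 ± 1.40 FPKM (adjusted p = 0.0250; list adjusted p = 0.110; 0.00629 to 0.854 over alternatives), a call lost without a filter, with the replicate block and without vector replicate 3, S37A replicate 2 or S37A replicate 3, while the 3 other scalings gave 2, 2 and 1 rising. The basal list was called up with the replicate block (adjusted p = 0.0434). Both epithelial lists were called up without vector replicate 3 (adjusted p = 0.0152 and 0.0142) and without S37A replicate 1 (adjusted p = 0.00236 and 0.00629). Of 14 endothelial markers limma called 0 by either count, with Emcn nearest at 76.1 ± 5.10 and 68.6 ± 1.61 FPKM (adjusted p = 0.0696; list adjusted p = 0.777), a fall called without vector replicate 1 and with sample weights. Of 6 glial and neural markers, 1 fell by either count, Mbp, from 2.49 ± 0.149 to 1.81 ± 0.125 FPKM (adjusted p = 0.0125; list adjusted p = 0.363), a call lost without S37A replicate 3 (adjusted p = 0.0519; 0.00210 to 0.0519 over alternatives).

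Notch pathway genes rose in 3 and fell in 1 of 10 cases by both counts. Hes1, a transcriptional effector of Notch, rose from 34.5 ± 3.58 to 68.3 ± 11.6 FPKM and the glycosyltransferase gene Lfng from 0.954 ± 0.147 to 2.19 ± 0.0546 FPKM (adjusted p = 0.00558 and 0.00231), and the list was called up (adjusted p = 0.00156; 0.111 with an estimated correlation; 0.000992 to 0.111 over alternatives). Among genes with a mean of at least 5 FPKM it was not called (adjusted p = 0.0603). The fall, of Notch1 from 2.21 ± 0.0396 to 1.88 ± 0.0270 FPKM (adjusted p = 0.0407), was not called with any 1 library left out, under any other scaling, with the replicate block or without a filter. Of 8 Hedgehog pathway genes, 1 fell by both counts, the receptor gene Ptch1, from 2.02 ± 0.341 to 1.36 ± 0.0739 FPKM (adjusted p = 0.0255; list adjusted p = 0.657), a call lost without any 1 of the S37A libraries, without a filter and under quantile normalization. Hedgehog genes under the 3 other scalings numbered 1, 1 and 0 rising and 1, 0 and 1 falling.

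Hypoxia and glycolysis genes rose in 6 of 18 cases and fell in 0, with 7 rising when adjusted over the list alone. Pfkp, a phosphofructokinase, rose from 19.8 ± 0.601 to 24.2 ± 0.625 FPKM (adjusted p = 0.00668), and the list was called up (adjusted p = 7.16e-06; 0.234 with an estimated correlation; 5.03e-07 to 0.234 over alternatives) but not by fry (adjusted p = 0.0557), with 10, 8 and 8 rising members under the 3 other scalings (the last among 16 genes) and with 1 rising member without vector replicate 2, S37A replicate 2 or S37A replicate 3, 2 with the replicate block, and 3 without a filter or without the trend. Sterol synthesis genes rose in 3 and fell in 1 of 18 cases by both counts (list adjusted p = 0.0116; 0.342 with an estimated correlation; 0.00532 to 0.342 over alternatives). That call was lost with sample weights (adjusted p = 0.0603) and by fry (adjusted p = 0.321). The sterol list had a median log2 difference of only 0.03, against -0.07 for all genes. The 3 other scalings gave 4, 4 and 4 rising and 0, 0 and 0 falling sterol genes. Without S37A replicate 3 limma called 0 of them, and without S37A replicate 2 or with the replicate block it called 0 lower. Unfolded-protein and amino-acid stress genes rose in 3 and fell in 4 of 19 cases by both counts. Trib3 fell from 30.4 ± 2.20 to 21.4 ± 1.11 FPKM and Pdia6, a chaperone of the endoplasmic reticulum, rose from 143 ± 5.61 to 169 ± 1.84 FPKM (adjusted p = 0.00494 and 0.00815). Camera did not call those genes as a list (adjusted p = 0.771) and fry called them down (adjusted p = 0.0238; 0.0238 to 0.940 over alternatives). Without vector replicate 2, vector replicate 3, S37A replicate 2 or S37A replicate 3, 1 of them rose and 2 fell. Without a filter, without the trend or with the replicate block, 1 rose. Under the 3 other scalings there were 4, 3 and 3 rising and 2, 3 and 3 falling, the last among 17 genes.

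Androgen-regulated genes rose in 3 and fell in 1 of 9 cases by both counts, with the kinase gene Sgk1 at 130.3 ± 7.39 and 166 ± 3.91 FPKM (adjusted p = 0.00607). Camera called that list up (adjusted p = 0.0212; 0.162 with an estimated correlation; 0.0144 to 0.514 over alternatives). Its median log2 difference was only 0.01, against -0.07 for all genes. Androgen-regulated genes were not called under median-ratio scaling (adjusted p = 0.0577), without the 100 most abundant genes (adjusted p = 0.0700), without vector replicate 2 (adjusted p = 0.0537), with 1 transcript model per gene (adjusted p = 0.514) or by fry (adjusted p = 0.0709). The fall, of Tsc22d3, was lost under each other scaling, without a filter, with the replicate block and without vector replicate 2, vector replicate 3, S37A replicate 2 or S37A replicate 3. Adipogenic genes rose in 2 and fell in 2 of 12 cases, or 2 and 4 adjusted over the list alone. Cd36 rose from 0.748 ± 0.117 to 1.63 ± 0.105 FPKM and Cebpd fell from 16.4 ± 1.11 to 10.8 ± 0.561 FPKM (adjusted p = 0.00409 and 0.00340; list adjusted p = 0.524). For adipogenic genes 1 member rose without vector replicate 3 or any 1 of the S37A libraries, without a filter, with a mean of at least 5 FPKM, with the replicate block or with 1 transcript model per gene, and 1 fell without vector replicate 3 or under median-ratio scaling.

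Bone and cartilage genes rose in 2 of 7 cases by both counts, with Tnfrsf11b, the decoy receptor osteoprotegerin, at 11.6 ± 1.24 and 17.9 ± 0.311 FPKM (adjusted p = 0.00445; list adjusted p = 0.0129; 0.360 with an estimated correlation; 0.00201 to 0.488 over alternatives). The other, Mgp, was lost without a filter, with the replicate block and without vector replicate 2, vector replicate 3, S37A replicate 2 or S37A replicate 3. The list was lost without a filter (adjusted p = 0.488), under median-ratio scaling (adjusted p = 0.0620) and by fry (adjusted p = 0.275). Ribosomal protein genes fell in 3 of 24 cases, or 0 adjusted over the list alone, with Rps3 at 378, 401 and 397 FPKM in vector and 335, 363 and 359.5 FPKM in S37A (adjusted p = 0.0391), itself lost under each other scaling, without a filter, without the trend and with any 1 library but vector replicate 1 left out. Camera called that list down (adjusted p = 0.0206; 0.683 with an estimated correlation; 0.000411 to 0.683 over alternatives). Ribosomal genes were not called under median-ratio scaling (adjusted p = 0.0988), without the 100 most abundant genes (adjusted p = 0.0750), or without vector replicate 2, vector replicate 3 or S37A replicate 1 (adjusted p = 0.0904, 0.0932 and 0.123), or by fry (adjusted p = 0.163). The number of ribosomal protein genes called was 0, 1 and 0 under the 3 other scalings (the last among 17 genes), 7 without vector replicate 1, and 0 without vector replicate 2, vector replicate 3, S37A replicate 1 or S37A replicate 3, without a filter or without the trend. With sample weights it was 13, and 5 with the replicate block or with GC and length trends removed.

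Over all settings, in some of which fewer or more members are tested, the numbers of called list members ranged as follows, with lists left out where none was called in any setting. The filter of 5 FPKM leaves 1 Wnt feedback gene, 1 macrophage marker and 3 Notch genes, which sets their lowest numbers. Rising members of the Wnt, TGF-β and growth factor lists: Wnt feedback 1 to 7, other Wnt targets 1 to 9, Wnt ligands 0 to 4, Wnt receptors 2 to 5, TGF-β ligands 4 to 6, TGF-β response 2 to 10, BMP 4 to 6 and growth factors 4 to 8. For muscle, matrix, cycle and immune lists the rising members were: smooth muscle 5 to 15, skeletal muscle 1 to 2, pericyte 2 to 3, matrix 4 to 12, proteases 2 to 6, p53 0 to 5, inflammatory 2 to 7, interferon 1 to 18 and macrophage 1 to 11. Among the other lists, rising members numbered: androgen 0 to 3, adipogenic 1 to 2, bone and cartilage 1 to 3, Hedgehog 0 to 1, Notch 1 to 4, hypoxia 1 to 10, sterol 0 to 4, stress 1 to 4, immediate-early 3 to 6, basal 0 to 1, luminal 0 to 2 and glial 0 to 1. Falling members of the first group ranged: other Wnt targets 1 to 5, Wnt ligands 0 to 1, Wnt receptors 0 to 2, TGF-β ligands 1 to 3, TGF-β response 0 to 1, BMP 0 to 1 and growth factors 2 to 4. In the second group they ranged: matrix 0 to 2, proteases 3 to 5, cell cycle 11 to 33, p53 1 to 5, inflammatory 6 to 9 and interferon 0 to 1. In the third they ranged: androgen 0 to 1, adipogenic 1 to 4, Hedgehog 0 to 3, Notch 0 to 1, sterol 0 to 1, stress 2 to 6, immediate-early 2 to 6, endothelial 0 to 3, glial 0 to 1 and ribosomal 0 to 13.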

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

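The rule for the values in this part was set after the data were seen: list members below the expression filter, and so outside the comparisons of the report, whose adjusted p in limma without a filter was under 0.05 and whose value was higher in every S37A library than in every vector library. Genes lower in S37A were not looked for. Sfrp2 went from 0.0626 to 0.224 FPKM, Tnfrsf19 from 0.0392 to 0.095 FPKM, Wnt4 from 0.222 to 0.411 FPKM and Lgr5 from 0.0261 to 0.0761 FPKM. Tnf went from 0.0563 to 0.239 FPKM, Itgam from 0.127 to 0.274 FPKM and Il1a from 0.12 to 0.178 FPKM. The adjusted p-values from limma without a filter ran from 0.0199 for Sfrp2 to 0.0436 for Il1a. Values this low rest on few fragments. No explanation was tested for these genes, and with 3 libraries per group single libraries were not tested for lying apart.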

How the results depend on the processing

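The alternatives with 1 transcript model per gene, with GC and length trends removed and with matched random lists were chosen after seeing the data. Over all results and alternatives, 2850 values kept their direction and their side of the threshold (counts within 1.5 times, untested values within 1 SD), 228 lost it, 37 gained it, and 32 counts moved further.

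Reversed directions were 28. The stress gene list, up without a call by camera, was called down by fry (adjusted p = 0.0238), since fry does not compare a list with other genes. All the others were of results called neither way, and their cause was not tested. The inflammatory list turned up without a filter (adjusted p = 0.8908), with at least 5 FPKM (0.7597), sample weights (0.8311), without vector replicate 1 (0.9401) or 2 (0.8472), and with GC and length trends removed (0.9928). Turning down with at least 5 FPKM were the adipogenic (0.437), Hedgehog (0.8778) and endothelial lists (0.7597). The stress list turned down under quantile normalization (0.7511) and without vector replicate 1 (0.9401), the endothelial list without vector replicate 1 (0.5368) or S37A replicate 1 (0.7818), and the adipogenic list with 1 transcript model per gene (0.626). By fry the p53 (0.4288), adipogenic (0.3331), Hedgehog (0.3331), endothelial (0.5389) and glial lists (0.7889) were down. Abcc9 had log2 differences of 0.018 with median-ratio scaling, 0.0432 with quantile normalization, 0.0107 with sample weights, and 0.0353 and 0.0007 without vector or S37A replicate 2. Tnnt3 had -0.0091 and -0.0408 without vector or S37A replicate 3, and Krt17 -0.0053 without S37A replicate 2. With 1 library left out these adjusted p-values ranged from 0.4859 to 0.9578 for the inflammatory, 0.6062 to 0.9401 for the stress and 0.1517 to 0.9428 for the endothelial list, and the log2 differences from -0.0753 to 0.0353 for Abcc9, -0.0408 to 0.2385 for Tnnt3 and -0.0053 to 0.4039 for Krt17.

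At 2-fold, where 16 genes were higher and 10 lower, a pseudocount of 0.1 gave 49 and 25, a pseudocount of 0.5 gave 27 higher, a mean of at least 5 FPKM gave 6 and 5, sample weights gave 29 and 20, genes with 1 transcript model gave 6 lower, and transcript models kept apart gave 34 and 25. A smaller pseudocount enlarges log2 differences at low FPKM, and the 5 FPKM filter tests fewer genes. For the others the cause was not tested.

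Without a 2-fold limit, where 729 genes were higher and 2393 lower, median-ratio scaling gave 1243 and 978, quantile normalization 1094 and 957, removal of the 100 most abundant genes 1522 lower, sample weights 1238 and 3655, and transcript models kept apart 381 and 770. Both scalings move the centre of all genes toward 0. For sample weights and separate models the cause was not tested.

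The Wnt ligand list was not called with a mean of at least 5 FPKM (adjusted p = 0.299) or 1 transcript model per gene (adjusted p = 0.09998), where fewer genes are tested, and the growth factor list was not called under quantile normalization (adjusted p = 0.0547) or by fry (adjusted p = 0.702). With an estimated correlation camera called 0 of the 32 lists, with 12 at an unadjusted p under 0.05: adjusted p was 0.0950 for Wnt feedback, 0.213 for Wnt ligands, 0.116 for TGF-β ligands and 0.111 for growth factors. Fry called 15 lists. The cause was not tested.

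With 1 library left out the counts ranged from 298 to 747 higher and 606 to 2401 lower, and at 2-fold from 17 to 22 and 9 to 13; fewer samples enter each fit. The lowest counts with no 2-fold limit came when S37A replicate 3 was left out. Ctnnb1 ranged from 0.28 to 0.40 on the log2 scale, not called without S37A replicate 2 (0.33) or 3 (0.32). List adjusted p-values ranged from 1.29e-07 to 2.85e-06 for Wnt feedback, 0.000607 to 0.00670 for TGF-β ligands, 0.00225 to 0.0109 for Wnt ligands and 0.00141 to 0.0152 for growth factors, and 20 to 24 lists were called.

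The replicate block gave 442 higher and 1193 lower genes, and 17 and 9 at 2-fold, and called the basal epithelial list (adjusted p = 0.0434). Deviations from the group means of same-numbered libraries correlated at -0.12, 0.021 and 0.104, and not every library correlated best with its own number, so the numbers are not taken to pair the samples.

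Inferred depth, from 40.7 to 51.0 M fragments, was lower in S37A in all but 1 comparison of a vector with an S37A library, and limits statements about genes below 0.5 FPKM.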

Other observations

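Tests chosen or changed after the result was seen were the matched random lists for the myeloid markers, the removal of the 100 most abundant genes as a test of the split, the second condition of the scaling test, the test of background on the falls of called genes, and the reading of the tests on blood cell genes, the 100 most abundant genes, and GC content and length as undecided; the lists of other myeloid and other blood genes were chosen without their values but after the rise of macrophage markers had been seen.

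All splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split was the 1 of 10 with as many genes higher (729, highest other 2), as many lower (2393, highest other 2), as many higher at 2-fold (16, highest other 2) and as many lower at 2-fold (10, highest other 2). For the number of gene lists called, 2 of 10 splits gave as many: 23 in the real split and 23 with vector replicate 1, S37A replicate 1 and S37A replicate 3 set against the others. The other splits called from 4 to 23 lists, though none called more than 2 genes in a direction. Camera with the preset correlation thus called lists where almost no gene was called. Each of the other splits leaves part of the group difference in place, with 2 libraries of 1 group on one side.

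Myeloid markers were higher in S37A. Log2 ratios of lists in this paragraph have 0.05 FPKM added to both means. Random lists matched on mean FPKM reached the median of the macrophage list in 0% of draws. This test was written after the rise of that list was seen, so its outcome was hardly in doubt. The matched lists had a median of -0.10, so genes at like levels did not rise in general. Background that differs between genes of the same level was not tested. Lymphoid, mast cell and red cell genes had a median log2 ratio of -0.26, but 14 of the 15 above 0 had a mean under 0.1 FPKM, matched random lists had a median of -0.15, and 90.2% of them were as high. Genes this near 0 exclude nothing, so the bound of 0.2 set beforehand was not used and a general rise of blood cells stays open. In a list of 36 other myeloid genes, 32 had a higher mean in S37A and 22 had every S37A library above every vector library. The median log2 ratio was 0.43, with 0% of matched lists as high, and 13 of the 36 had a mean under 0.1 FPKM. That median missed the bound of 0.5, set without its value, for a larger share of macrophages. The bound was set for ratios with 0.05 FPKM added, which draws ratios of genes near 0 toward 0, so the miss decides little. More macrophages and a change of these genes within the cells cannot be told apart. The replating step keeps attached cells, which may include macrophages. Ccl2 and Ccl7, which attract monocytes, were lower in S37A, and whether this bears on the myeloid markers was not tested.

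More genes were lower than higher in S37A, 76.7% of calls. The tests run do not decide why. Under quantile normalization the share was 46.7%, but centring itself pulls the split toward even. An even split was at first taken to point to scaling; a condition was then added that the median difference be alike at all levels of FPKM, and the medians, from -0.09 at 2 to 5 FPKM to -0.04 at 100 FPKM and above, missed it. Without the 100 most abundant genes the share was 62.5%, but that setting also brings each library to a common sum, and the share follows the shift of all genes, whose median went from -0.07 to -0.04. With GC and length trends removed the share was 79.4%, but the centre of each library was put back in that setting, so the share could hardly change. Scaling, the most abundant genes, GC content and length, and a broad small fall therefore cannot be told apart. Signal at the lowest levels was also lower in every S37A library: of 1120 olfactory receptor genes, 107, 129 and 103 were above 0 in the vector libraries and 76, 61 and 67 in S37A, and genes with a mean under 0.1 FPKM summed to 146, 173 and 146 FPKM against 106, 110.5 and 105 FPKM. Called lower genes fell by a median of 1.63 FPKM, against a mean fall of 0.000424 FPKM per olfactory receptor gene and 0.00858 FPKM per gene with a mean between 0 and 0.1 FPKM. The smaller ratio, 189.8, lies far above the bound of 3 set for background after the values were seen. Called genes had already passed the filter and the test, and 0 of those lower fell by under 0.1 FPKM, so the ratio could hardly meet that bound. The values show only that an even background of the size seen in near-silent genes is smaller than the fall of each called gene. Background that follows the level of a gene was not tested.

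Some transcript models were listed at 0 in every library of 1 group and at 1 FPKM or more in every library of the other: 30 models of 28 genes, 15 at 0 in S37A and 15 at 0 in vector. All of them, 100%, overlapped another model, against 59.5% of 5317 models at the same level. The summed values of 25 of the 28 genes differed by less than 0.5 on the log2 scale. The exceptions were Clk2-scamp3, Ppip5k1 and 2700081O15Rik, whose sums differed by -3.29, -1.77 and -2.56. Other splits of the libraries gave up to 21 such models. For the 25 genes these values go with reads moving among overlapping models of a gene in the estimation. The listed 0 of Ppip5k1 and Clk2-scamp3 may have a like source only if their reads moved to overlapping models of other genes. Map1a was higher in S37A, at 11.6, 11.2 and 11.2 FPKM against 9.84, 8.80 and 8.93 FPKM, and Scamp3 at 81.2, 82.7 and 84.2 FPKM against 75.3, 69.2 and 72.4 FPKM. No biological explanation was tested for this pattern; for the others the S37A group itself stays open, untested.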
